A study of Homo sapiens with 4 samples.

How the data were processed

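RNA from MCF-7 cells, an established oestrogen receptor positive breast cancer line, was sequenced after transfection with a control siRNA (siControl) or with an siRNA against TRIM46 (siTRIM46), in 2 libraries per group. The design text says only that each group was repeated, and nothing in the labels says that the repeats were separate cultures, so p-values measure only the spread between these 4 libraries, which may be technical. The groups and the replicate numbers 1 and 2 came from the sample titles. The sequence of the siRNA was not given in the sources used here, nor whether both siTRIM46 libraries received the same siRNA.

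The deposited values were FPKM per gene (fragments mapped to a gene, scaled to transcript length and to all mapped fragments), per the file headers, printed with 2 decimals beside a gene symbol and an Entrez identifier. HISAT2 2.1.0, Bowtie2 2.2.5 and the builds GRCh38.p11 and hg38 were named per the submitters' processing notes, with no role for either tool. The program that computed FPKM, the gene annotation and the use of strand were not given in the sources used here. Reads of overlapping genes, read-through genes and close paralogs may therefore have been divided in an unknown way, and such genes are given as uncertain. FPKM keeps no total of reads, and the commonest ratios of low values between libraries were mostly values printed equal, so no read step was recovered. Depth was unknown, no interval for counting error was given, and the column sums were not a measure of depth. Both replicate 1 libraries listed the same 17509 genes in the same order, and both replicate 2 libraries the same 17881 genes. The names of the value columns also followed a different pattern in the 2 pairs. Libraries of the same number were therefore treated as a possible processing batch, called a file pair here, and values within each file pair were computed beside the pooled ones.

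Genes listed in all 4 libraries (17146) were kept. A further 363 genes were listed only for replicate 1 and 735 only for replicate 2, of which 1 had a mean of at least 1 FPKM in its pair. Symbols that had been turned into calendar dates (22 of the tested genes) were restored through the Entrez identifier. The table of RefSeq genes matched 16865 of the 17146 identifiers. Values were analysed as log2(FPKM + 1), and genes with a mean of at least 1 FPKM over the 4 libraries were tested (12068 genes). A log2 fold change on the log2(FPKM + 1) scale understates the change of low genes. The test was limma 3.58.1 with an intensity trend in R 4.3.3, two-sided, with no covariate, and Benjamini-Hochberg adjustment at 0.05. The design had foreseen a test on read counts for the case that counts were deposited and limma for normalized values, so the latter applied. TRIM46 itself, with a mean of 0.998 FPKM, lay just under the filter and was compared by a two-sided exact permutation test.

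The design, the tests, 35 gene lists, the rule for naming genes and most alternative settings were fixed before the data were examined. Of the lists, 33 had at least 3 tested genes and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The TRIM46 relatives (2 tested genes) and the endothelium markers (1 tested gene) had too few. The tests with an estimated correlation and with fry, which asks whether the genes of a list move one way without comparing them with other genes, were alternatives. With 4 libraries the first has few residual degrees of freedom, so a call lost there cannot be put down to correlation between genes alone. For differences of lists between replicate numbers, the direction given is that of the median, as that of the test was not recorded. The naming rule took TRIM46, then the 12 genes with the largest rise and the 12 with the largest fall among those that passed. Where fewer than 5 passed, it took the 12 in each direction with the smallest unadjusted p, a mean of at least 1 FPKM and groups that did not overlap. It also took 2 members of each list with the smallest p where none passed, all members of the DNA replication machinery list, HDAC1, and the relatives and chromosomal neighbours of TRIM46. Genes named outside the rule are said to have been chosen after their values were seen.

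Other settings were a replicate block, median scaling, quantile normalization, no filter, a mean of at least 5 FPKM, limma without trend, a pseudocount of 0.1, other thresholds, and each library left out in turn. A threshold of 0.10, a replicate block together with an estimated correlation, and a test without genes carrying CCTGAC in the 3′ untranslated region (UTR) were added after the data had been seen. Gene coordinates, transcript sequences, lengths and GC content came from GENCODE 29 on GRCh38, with 1 transcript per gene, that with the longest coding sequence. A transcript was found for 11895 tested genes and a 3′ UTR of at least 50 bases for 11412; the other 656 were not searched for sites. All words of 7 bases found in at least 20 genes were scored. First, a fit of the log2 fold change on UTR length and base content, transcript length, GC content and level was removed. The score z was the mean remainder of genes with the word over its standard error. Site classes, coding sequences and base composition were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

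The steps were tested on simulated data with 200 changed genes among 12068 in 10 runs. Without a difference between file pairs, the test recovered 77.5% of genes changed by a log2 fold of 1 and 99.7% of those changed by 2. With a difference between file pairs like the one in these libraries, it recovered 0% and 60.2%, and a fit with the replicate number as a term recovered 84.3% and 99.6% with 24.3 false calls per run. Camera called a planted list in 20 of 20 runs and 1 of 640 lists without a shift. In these runs genes varied independently and no difference between file pairs was added. They give no rate of false calls for correlated lists, such as the DNA replication list here (estimated correlation 0.445). A planted word ranked first in 10 of 10 runs. With 2 libraries per group no outlier test and no test over other splits of the libraries was made.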

Results

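The transcriptome of MCF-7 cells, an oestrogen receptor positive breast cancer line, was measured by RNA-seq after transfection with a control siRNA (siControl, n = 2 libraries) or with an siRNA against TRIM46 (siTRIM46, n = 2), a gene of the tripartite motif family. FPKM values summed to 490855 and 450792 in siControl 1 and 2, and to 507079 and 471276 in siTRIM46 1 and 2. At least 1 FPKM was reached by 11651 and 12076 genes in the siControl libraries and by 11839 and 12342 genes in the siTRIM46 libraries. The depth was unknown. KRT8, a keratin of luminal epithelium, had the highest value in both siControl libraries (4901.7 and 7077.08 FPKM), RPL41 in siTRIM46 1 (5156.68 FPKM) and EEF1A1 in siTRIM46 2 (4532.57 FPKM); these 3 genes were chosen after their values were seen, and KRT8 shares exons with KRT18, so its value is uncertain. The first principal component held 58.85% of the variance and placed both siControl libraries (scores −36.5 and −14.8) below both siTRIM46 libraries (11.4 and 39.9). The second held 34.46% and placed each replicate 2 library (−32.2 and −6.84) below both replicate 1 libraries (13.5 and 25.5).

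TRIM46 mRNA (Entrez 80128) was low in all 4 libraries and lower in siTRIM46. Its level was 1.23 and 1.13 FPKM in siControl 1 and 2, and 0.84 and 0.79 FPKM in siTRIM46 1 and 2. The mean of 0.815 ± 0.0354 FPKM (SD, n = 2) in siTRIM46 was 69.1% of the mean of 1.18 ± 0.0707 FPKM (SD, n = 2) in siControl, and the level was 68.3% and 69.9% within the first and the second file pair (the libraries of replicate number 1 and 2, which were listed with different sets of genes). Both siTRIM46 libraries lay below both siControl libraries, with a two-sided exact permutation p of 0.333, the smallest that 2 against 2 libraries allow. With no filter on low values, limma gave a log2 fold change of −0.26 and an adjusted p of 0.414. TRIM46 lies on chromosome 1 at 155173787 to 155184971 of GRCh38 on the plus strand; its transcript has 10 exons and no exon shared with another annotated gene.

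The main comparison asked which mRNAs differed between siTRIM46 and siControl cells. The genes with the smallest p on the lower side included MCM5, a subunit of the replicative helicase, NCAPD2, a subunit of condensin, and PKMYT1, a kinase that inhibits CDK1. MCM5 was at 36.1 ± 2.86 FPKM in siControl and 8.77 ± 2.08 FPKM in siTRIM46 (SD, n = 2 each), 4.11-fold lower. NCAPD2 was 4.37-fold lower (42.6 ± 1.90 against 9.73 ± 2.79 FPKM) and PKMYT1 4.69-fold lower (26.9 ± 2.52 against 5.74 ± 1.44 FPKM). On the higher side stood RNASE4 and ANG, neighbouring genes for secreted ribonucleases. RNASE4 was at 1.03 ± 0.410 FPKM in siControl and 29.9 ± 18.3 FPKM in siTRIM46, and ANG at 1.48 ± 0.523 and 16.7 ± 7.07 FPKM. By limma, 0 of 12068 genes passed an adjusted p of 0.05, the smallest adjusted p being 0.0857. At an unadjusted p under 0.05 there were 2146 genes (962 higher and 1184 lower), against 603 by chance, a number that takes no account of the file pairs. With the file pair as a term in the limma fit, 3347 genes passed (1715 higher and 1632 lower), of which 618 differed by 2-fold or more. Leaving out a library gave 162 genes without siControl 1, 365 without siControl 2, 733 without siTRIM46 1 and 170 without siTRIM46 2.

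The log2 fold changes of the 2 file pairs, which share no library, followed each other across genes (Spearman 0.747, Pearson 0.763 over 12068 genes, which are not independent replicates). The sign was the same in both pairs for 9452 genes (78.3%). In both pairs, 131 genes were at least 2-fold higher and 234 at least 2-fold lower in siTRIM46. The groups did not overlap for 5961 genes (49.4%). By chance this would be 33.3% if there were no difference between file pairs, which these libraries do have. The median log2 fold change of all tested genes was 0.04.

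**Figure D1:**
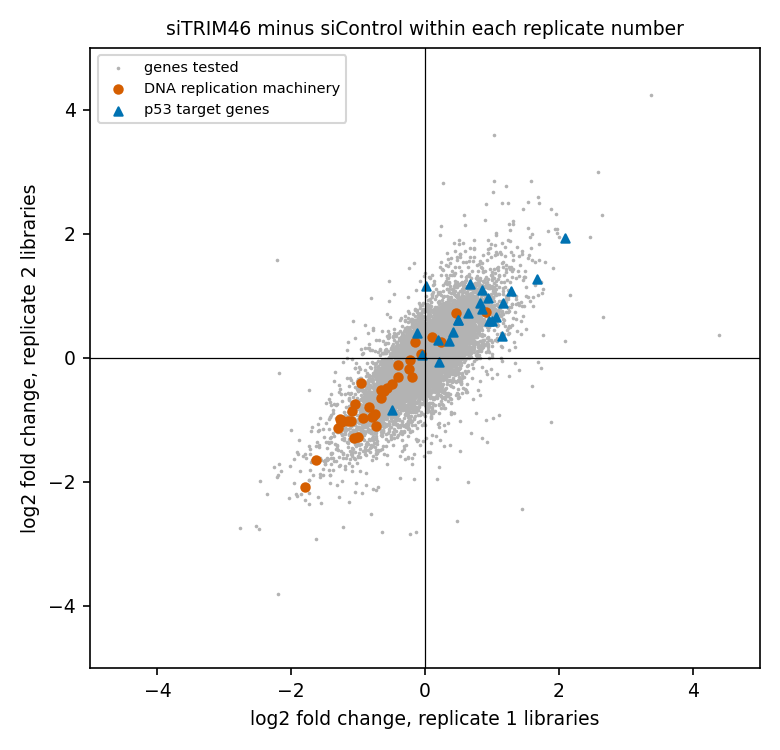
Log2 fold change of siTRIM46 against siControl on the log2(FPKM + 1) scale for each of the 12068 tested genes in the first file pair (x axis) and the second (y axis), with genes of the DNA replication machinery and p53 target lists marked. Most replication genes lie at negative values and most p53 targets at positive values in both pairs.

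Each of the 12 named genes on the lower side missed the test over all genes (limma adjusted p 0.0857) and passed with the file pair as a term. They were 3.01 to 19.9-fold lower by their mean FPKM. DHRS2, a short-chain dehydrogenase gene on chromosome 14 (23630115 to 23645639), was 19.9-fold lower (8.74 ± 0.926 against 0.440 ± 0.127 FPKM; log2 fold change −2.76, SE 0.23). CHPF, which encodes a chondroitin polymerizing factor on chromosome 2 (219538947 to 219543787), was 7.12-fold lower (39.2 ± 4.68 against 5.51 ± 0.163 FPKM; log2 fold change −2.62, SE 0.19). MCM5, on chromosome 22 (35400063 to 35425430), had a log2 fold change of −1.80 in the first and −2.08 in the second file pair. CYB5R3, a cytochrome b5 reductase, stood at 43.5 FPKM in siControl and 9.60 FPKM in siTRIM46, and CDC34, a ubiquitin-conjugating enzyme, at 31.7 and 9.14 FPKM. LDLRAP1, an adaptor of the LDL receptor, stood at 12.1 and 3.03 FPKM, and PCTP, a phosphatidylcholine transfer protein, at 11.9 and 2.09 FPKM. HN1, TMEM189 and YWHAH were at 82.1, 63.3 and 63.9 FPKM in siControl and at 16.3, 21.01 and 18.2 FPKM in siTRIM46. The 3′ UTRs of 7 of the 12 genes carried the word CCTGAC (CHPF, CYB5R3, CDC34, LDLRAP1, NCAPD2, TMEM189 and YWHAH). Of all 11412 searched genes, 7786 did not carry it. Exons of CHPF, PKMYT1, NCAPD2, TMEM189 and YWHAH overlap those of other genes, so their values are uncertain.

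On the higher side the 12 named genes also missed the test (limma adjusted p 0.0857 to 0.0875) and all passed with the file pair as a term. RNASE4, on chromosome 14 (20684100 to 20701215), had a log2 fold change of 3.80 (SE 0.44) and ANG one of 2.79 (SE 0.34); their exons overlap, so the division of reads between them is uncertain. CALML5, a calmodulin-like gene of epithelia, was at 26.8 ± 1.12 FPKM in siControl and 82.4 ± 13.4 FPKM in siTRIM46. HSD17B14, a hydroxysteroid dehydrogenase, was at 1.43 ± 0.453 and 8.96 ± 2.33 FPKM, and ST6GALNAC6, a sialyltransferase, at 10.8 ± 1.07 and 31.2 ± 1.62 FPKM. C11orf71, TPRG1L, C6orf52, LIMD2 and TCTA had log2 fold changes of 1.99, 1.59, 2.14, 2.1 and 1.58; exons of C11orf71, C6orf52, LIMD2 and ST6GALNAC6 overlap other genes, and these values are uncertain. The read-through genes RPS10-NUDT3 (listed at 0 in both siControl libraries, 4.52 and 2.87 FPKM in siTRIM46) and C7orf55-LUC7L2 (5.17 and 15.8 FPKM) share exons with their parent genes and are uncertain. CCTGAC was present in the 3′ UTR of 3 of the 12, within CCTGACA in LIMD2 and within GCCTGAC in RPS10-NUDT3 and TCTA. C6orf52 was not searched.

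The series title concerns DNA replication, and 9 lists of replication and repair genes were the primary lists. By camera at the preset correlation 4 of them were lower, 1 (nucleotide excision repair) was higher and 4 did not pass. The 35 genes of the DNA replication machinery, which encode the replicative helicase, polymerases, clamp, clamp loader and associated factors, were lower as a group in siTRIM46. The median log2 fold change was −0.82 (−0.75 in each file pair), and 29 of the 35 were lower in both file pairs. RFC5, a clamp loader subunit, was 3.33-fold lower (31.8 ± 4.50 against 9.55 ± 1.58 FPKM). POLA2 and POLA1, subunits of the priming polymerase, stood at 27.2 ± 1.27 and 9.20 ± 1.02 FPKM in siControl and at 11.1 ± 0.460 and 3.66 ± 0.163 FPKM in siTRIM46. The helicase genes MCM2, MCM3, MCM4, MCM6 and MCM7 had log2 fold changes of −1.14, −0.86, −1.14, −1.12 and −1.18, and PCNA, the sliding clamp, one of −0.53. POLD4 and RPA3 were higher in both file pairs, with log2 fold changes of 0.82 and 0.59. Of the 35 genes, 20 were lower and 0 higher adjusted over the list alone by limma, and 0 passed over all genes tested. With the file pair as a term, 24 were lower and 2 (POLD4 and RPA3) higher over all genes. The DNA replication list passed camera (adjusted p = 1.19e-10), but its adjusted p = 0.664 with an estimated correlation, and its fry adjusted p was 0.251. The list was also lower in the replicate 2 than in the replicate 1 libraries (median log2 difference −0.26, camera adjusted p 1.36e-05, but 0.784 with an estimated correlation). CCTGAC lay in the 3′ UTR of 8 of its genes, among them POLA1 and POLA2, which were lower, and POLD4, which was higher. Of its genes 26 were searched and had none, against 7786 of all 11412 searched genes. Values of RFC5, POLA2, MCM2, MCM7, RPA3 and POLD4 are uncertain because their exons overlap those of other genes.

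**Figure D2:**
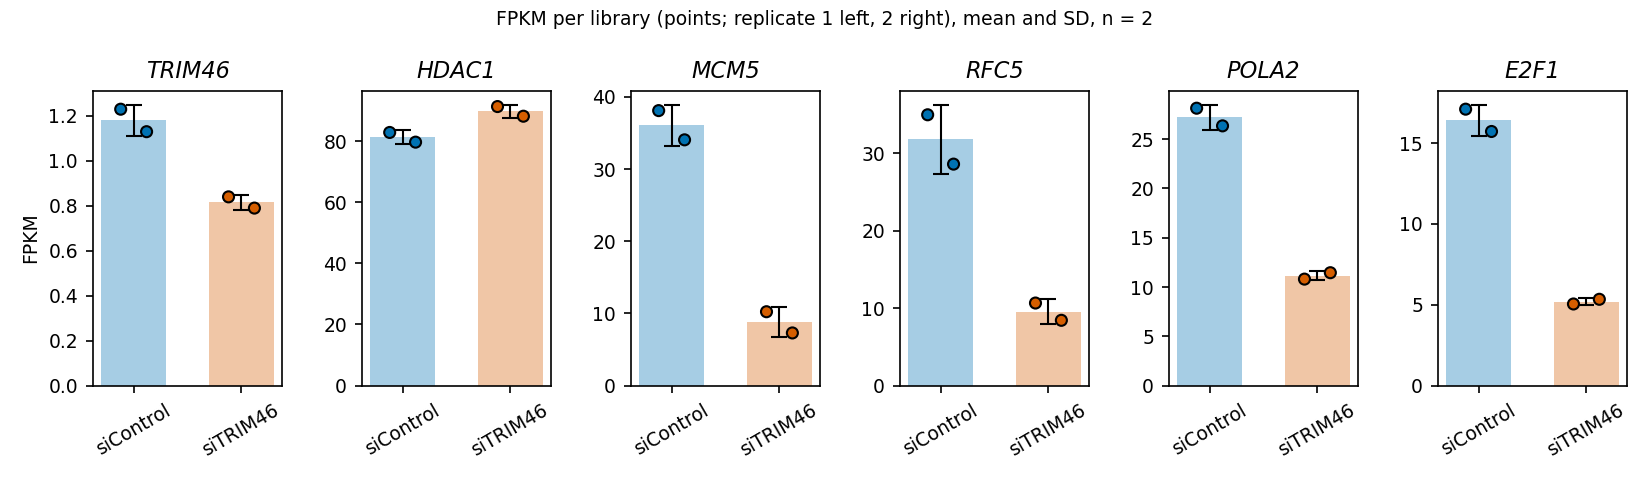
FPKM of TRIM46, HDAC1, MCM5, RFC5, POLA2 and E2F1 in siControl and siTRIM46 (bars, mean; error bars, SD, n = 2; points, single libraries with replicate 1 on the left and replicate 2 on the right). Both siTRIM46 points lie below both siControl points for every gene but HDAC1, where they lie above.

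**Figure D3:**
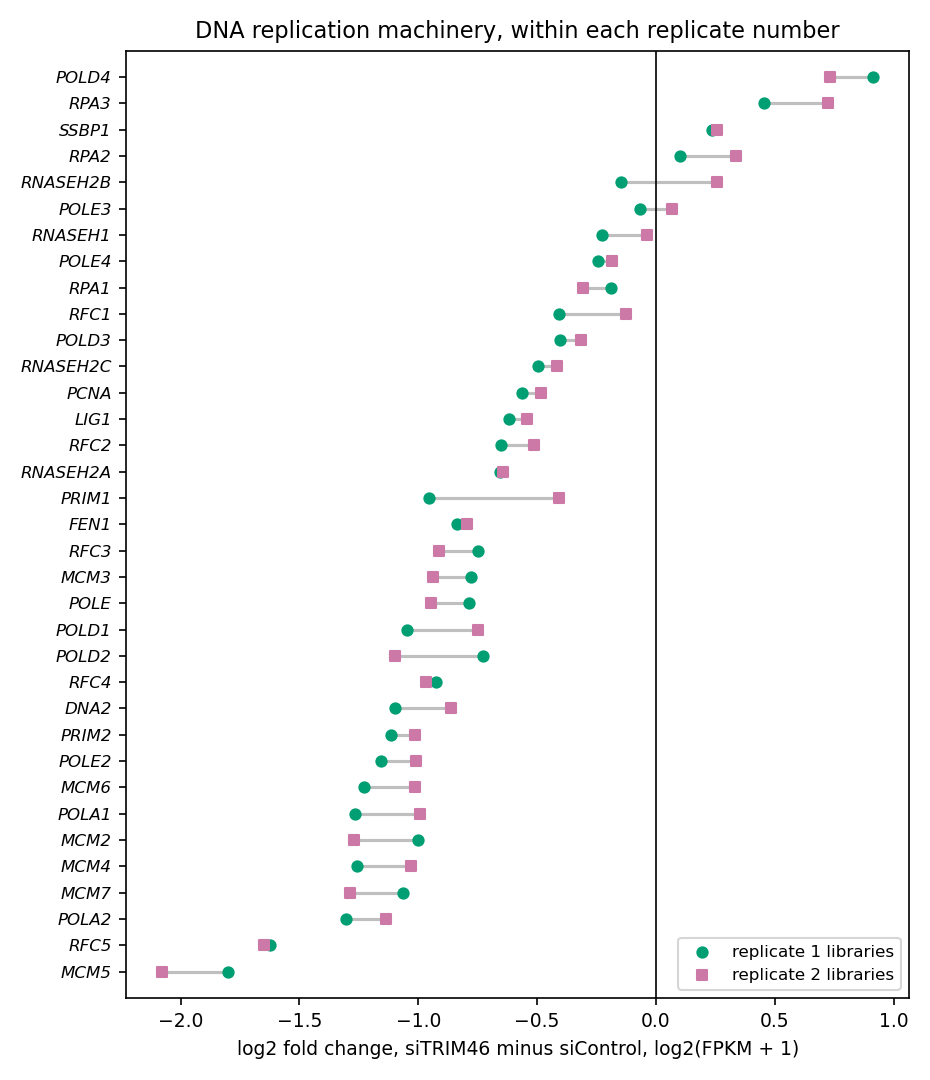
Log2 fold change (siTRIM46 against siControl, log2(FPKM + 1) scale) of the 35 genes of the DNA replication machinery list in each file pair. For 29 genes both values lie below 0.

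Genes of origin licensing and firing were lower as a group too, with a median log2 fold change of −0.61 (−0.70 and −0.63 in the file pairs; camera adjusted p 1.81e-06, but adjusted p = 0.664 with an estimated correlation). TICRR, a factor of origin firing, stood at 8.11 ± 0.742 FPKM in siControl and 2.82 ± 0.728 FPKM in siTRIM46, while ORC3, a subunit of the origin recognition complex, stood at 15.0 ± 0.912 and 30.01 ± 1.71 FPKM. Of the 26 genes, 14 were lower and 2 higher adjusted over the list alone. The 27 homologous recombination genes had a median of −0.65 (−0.69 and −0.65; camera adjusted p 1.19e-06, but 0.664 with an estimated correlation), with 15 lower and 1 higher adjusted over the list alone. EXO1, a resecting nuclease, was at 9.34 ± 1.26 and 2.04 ± 0.672 FPKM, and RMI2, a partner of the BLM helicase, at 52.2 ± 11.2 and 15.6 ± 3.51 FPKM. The 14 Fanconi anaemia genes had a median of −0.66 (camera adjusted p 0.000234, but 0.664 with an estimated correlation), with 6 lower and 0 higher adjusted over the list alone; FANCI stood at 35.5 ± 0.544 and 14.2 ± 0.70 FPKM and FANCD2 at 18.7 ± 1.42 and 7.83 ± 0.502 FPKM. In each of these lists 0 genes passed over all genes tested without the file pair, and 18, 17 and 8 were lower and 2, 2 and 0 higher with it. The licensing and homologous recombination lists were also lower in replicate 2 than in replicate 1 (median log2 differences −0.23 and −0.11, adjusted p 0.000387 and 0.0365, but 0.784 each with an estimated correlation).

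The remaining repair lists were divided. Nucleotide excision repair genes were higher as a group (20 genes, median 0.23, camera adjusted p 0.036). DDB2, which is also on the list of p53 targets, and CETN2 both act in the damage recognition step. They were at 45.4 ± 1.20 and 72.5 ± 10.3 FPKM in siControl and 90.2 ± 9.13 and 139 ± 7.52 FPKM in siTRIM46. Only these 2 genes of the nucleotide excision repair list passed adjusted over the list alone. Its adjusted p = 0.664 with an estimated correlation and 0.0528 with the file pair as a term, and it was 0.173 without siControl 2 and 0.1996 without siTRIM46 1. Mismatch repair (7 genes, adjusted p 0.819), base excision repair (18, 0.263), non-homologous end joining (14, 0.832) and the checkpoint kinases and mediators (15, 0.116) did not pass camera. Adjusted over the list alone, MSH6 was the 1 mismatch repair gene to pass, at 33.3 ± 3.12 and 16.1 ± 0.0283 FPKM.

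Cell cycle genes were lower in siTRIM46 and p53 target genes higher. Camera gave adjusted p values of 2.22e-13, 7.72e-11 and 1.53e-07 for the G2/M, G1/S and p53 lists, and for each the adjusted p = 0.664 with an estimated correlation. Every one of the 30 genes of G2/M and mitosis had a negative log2 fold change (median −1.001; −0.74 and −1.21 in the file pairs), and 14 passed adjusted over the list alone. TOP2A, the mitotic topoisomerase, stood at 62.5 ± 3.24 FPKM in siControl and 24.4 ± 4.26 FPKM in siTRIM46, and CDK1 at 41.8 ± 4.09 and 15.6 ± 4.98 FPKM. Of the 25 genes of G1/S and E2F targets, 24 had a negative value (median −0.92) and 17 passed adjusted over the list alone. E2F1 itself was 3.16-fold lower (16.4 ± 0.976 against 5.195 ± 0.205 FPKM), and UHRF1, a factor of maintenance methylation, 3.34-fold lower, with CCTGAC in its 3′ UTR. Of the 24 p53 targets, 23 had a positive value (median 0.76; 0.74 and 0.63 in the file pairs), with 12 higher and 1 lower adjusted over the list alone. BTG2, an antiproliferative gene, stood at 21.3 ± 7.79 and 88.0 ± 24.3 FPKM, and GDF15, a stress-induced cytokine, at 82.1 ± 5.48 and 168 ± 13.3 FPKM. With the file pair as a term, 27 G2/M genes and 18 G1/S genes were lower, and 16 p53 targets were higher and 1 lower, over all genes; without it 0 passed. The G2/M and G1/S lists were also lower in replicate 2 than in replicate 1 (median log2 differences −0.64 and −0.34, adjusted p 7.04e-11 and 4.34e-05, but 0.784 each with an estimated correlation).

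**Figure D4:**
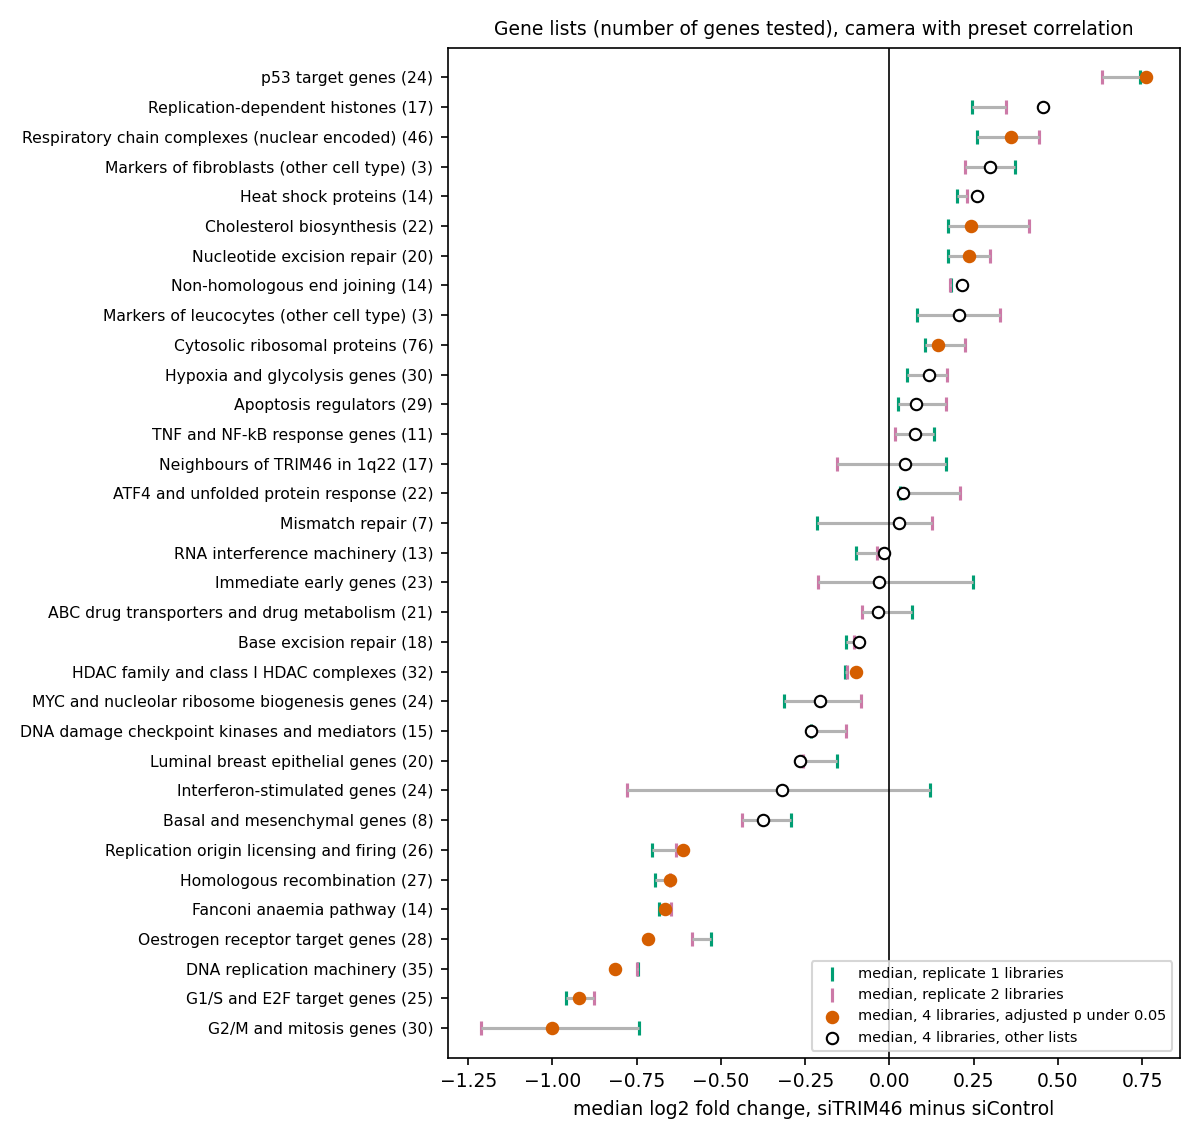
Median log2 fold change (siTRIM46 against siControl, log2(FPKM + 1) scale) of the 33 tested gene lists. Orange marks an adjusted p under 0.05 by camera at the preset correlation (8 lists lower, 5 higher). None held with an estimated correlation, a test with little power at 2 libraries per group.

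Oestrogen receptor target genes were lower as a group (28 genes, median −0.72; 10 lower and 3 higher adjusted over the list alone; camera adjusted p 0.000629, but adjusted p = 0.664 with an estimated correlation). CELSR2, a cadherin, stood at 95.3 ± 12.7 FPKM in siControl and 30.5 ± 0.898 FPKM in siTRIM46, and MYB at 26.9 ± 8.10 and 7.42 ± 2.40 FPKM. The receptor gene ESR1 was at 80.7 ± 11.5 and 49.98 ± 11.6 FPKM, and AR at 4.85 ± 1.17 and 9.07 ± 0.643 FPKM. Both belong to the luminal epithelial list, which did not pass (20 genes, median −0.27, camera adjusted p 0.164). The list of histone deacetylases and their complexes passed camera at the preset correlation (adjusted p 0.00929) with a small median of −0.10, but its adjusted p = 0.664 with an estimated correlation (32 genes, 25 with negative values, 2 lower adjusted over the list alone). Those 2 genes were HDAC11 (16.2 ± 2.55 and 5.65 ± 0.615 FPKM) and HDAC3 (31.3 ± 8.01 and 12.8 ± 1.25 FPKM), both with GCCTGACA in the 3′ UTR. Across this list the word did not go with a lower level. Its 7 genes with GCCTGAC or CCTGACA in the 3′ UTR had a median log2 fold change of −0.06. The median was −0.18 for its 18 genes with no CCTGAC there. HDAC1 was at 81.2 ± 2.24 FPKM in siControl and 89.7 ± 2.23 FPKM in siTRIM46 (log2 fold change 0.14, limma adjusted p 0.733). The oestrogen receptor targets also differed between replicate 2 and replicate 1 (camera adjusted p 0.0309, but 0.784 with an estimated correlation). Their median log2 difference was only −0.077, and the direction of the test was not recorded. MYB also carried CCTGAC in its 3′ UTR, and exons of MYB, HDAC11 and HDAC3 overlap other transcripts, as do those of TICRR, RMI2, FANCI, FANCD2 and MSH6.

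Genes of the respiratory chain, cholesterol biosynthesis and the cytosolic ribosome were slightly higher as groups, with 0 members passing adjusted over the list alone. With the file pair as a term, 22, 6 and 10 members were higher and 2, 0 and 2 lower over all genes. Camera gave adjusted p values of 0.000977, 0.00818 and 0.036, which became adjusted p = 0.895, 0.895 and 0.907 with an estimated correlation. The respiratory chain list (46 genes) had a median of 0.36, with 38 positive values; NDUFA8 stood at 52.0 ± 1.88 and 78.4 ± 3.13 FPKM, and NDUFB5, against the group, at 61.6 ± 6.44 and 32.5 ± 4.62 FPKM. The cholesterol list (22 genes) had a median of 0.24, with SQLE at 76.3 ± 23.9 and 131 ± 18.2 FPKM and SC5D at 5.40 ± 0.297 and 10.0 ± 0.106 FPKM. The 76 ribosomal protein genes had a median of 0.15, with RPS13 at 473 ± 96.5 and 648 ± 27.1 FPKM and RPS27A at 509 ± 69.9 and 363 ± 43.9 FPKM; exons of RPS27A overlap another gene and its value is uncertain. The ribosomal list no longer passed under median scaling (adjusted p 0.127) or quantile normalization (0.571), nor without siControl 2 (0.724, median −0.015) or siTRIM46 1 (0.922, median 0.041), where camera, which compares it with other genes, gave the opposite direction. Without siControl 2 the respiratory and cholesterol lists were at 0.636 and 0.442, and without siTRIM46 1 at 0.402 and 0.1996. The ribosomal, respiratory and cholesterol lists were lower in replicate 2 than in replicate 1 (median log2 differences −0.30, −0.25 and −0.16, adjusted p 8.73e-14, 3.17e-07 and 0.0161, but 0.784, 0.784 and 0.8215 with an estimated correlation).

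Other lists did not pass camera. Interferon-stimulated genes had a median of −0.32 (24 genes, adjusted p 0.0966), with 0.12 in the first and −0.78 in the second file pair. Nucleolar ribosome biogenesis genes (24, adjusted p 0.118) included MYC at 22.2 ± 2.79 and 8.54 ± 0.523 FPKM, the 1 member to pass adjusted over the list alone, and NOP56 at 56.4 ± 15.6 and 32.9 ± 3.03 FPKM. Immediate early genes (23, 0.767) had 1 higher and 4 lower adjusted over the list alone, with EGR1 at 7.59 ± 0.0849 and 2.09 ± 0.233 FPKM and CCTGAC in its 3′ UTR. Apoptosis regulators (29, 0.812) had 2 higher and 3 lower adjusted over the list alone, with BIRC5 at 32.6 ± 6.09 and 8.34 ± 4.43 FPKM and CASP2, whose 3′ UTR carried GCCTGACA, at 18.1 ± 0.269 and 8.69 ± 0.304 FPKM. Heat shock proteins (14, 0.767) included HSPB8 at 8.62 ± 0.240 and 1.5 ± 0.467 FPKM, again with GCCTGACA in its 3′ UTR. In the immediate early list, the 3 genes with GCCTGAC or CCTGACA in the 3′ UTR had a median log2 fold change of 0.48. It was −0.05 for the 16 with no CCTGAC there. In the apoptosis list the medians were −0.13 (8 genes) and 0.17 (16 genes). The hypoxia and glycolysis list (30, 0.481) included SLC2A1, a glucose transporter, at 55.6 ± 2.92 and 22.8 ± 7.81 FPKM, and the replication-dependent histones (17, 0.142) HIST1H2BK at 180 ± 37.8 and 339 ± 2.55 FPKM. Exons of NOP56 and SLC2A1 overlap other transcripts, so their values are uncertain. The lists of the unfolded protein response (22, 0.534), TNF and NF-kB response (11, 0.742), drug transport and metabolism (21, 0.812), RNA interference (13, 0.943) and basal and mesenchymal genes (8, 0.227) gave no call either. Median and mean had opposite signs for the mismatch repair, TNF, drug transport and TRIM46 neighbour lists; the test had the sign of the mean for the first pair of lists and that of the median for the last pair.

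Several calls changed with the library left out, which gives the groups unequal shares of the 2 file pairs. The changes followed the differences between file pairs in direction and cannot be told apart from them. Median differences of replicate 2 from replicate 1 were 0.76 for interferon-stimulated, 0.735 for basal and mesenchymal, 0.43 for immediate early and 0.58 for histone genes. They were −0.29 for nucleolar and −0.15 for checkpoint genes. Interferon-stimulated genes passed as lower without siControl 1 (adjusted p 4.93e-10) and without siTRIM46 2 (0.00168), and basal and mesenchymal genes likewise (0.0112 and 0.00656). Nucleolar genes passed as lower without siControl 2 (0.00177) and without siTRIM46 1 (0.0431), and histones as higher (0.0137 and 0.0249). Immediate early genes passed without siControl 1 (0.0246) and checkpoint genes without siControl 2 (0.0362).

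Relatives and neighbours of TRIM46 were listed as a check on its locus and family. MID2, a relative, stood at 8.43 ± 1.68 FPKM in siControl and 19.8 ± 1.53 FPKM in siTRIM46 (log2 fold change 1.15, limma adjusted p 0.111), and TRIM36 at 1.39 ± 0.141 and 3.50 ± 2.52 FPKM. MID1 was listed at 0.22 and 0.48 FPKM against 1.19 and 1.37 FPKM, and TRIM9 and TRIM67 stayed at or below 0.15 FPKM. Among the 17 tested neighbours in 1q22 the median was 0.05 (camera adjusted p 0.967), with 1 higher and 1 lower adjusted over the list alone. SCAMP3 was 3.91-fold lower (65.9 ± 17.3 against 16.8 ± 2.29 FPKM) and SLC50A1 was higher (90.1 ± 3.61 and 190 ± 42.5 FPKM). Both carried CCTGAC in the 3′ UTR. MUC1 differed more between the file pairs (238.05 and 240.17 FPKM in replicate 1, 99.83 and 73.81 FPKM in replicate 2) than between the groups; its exons overlap another transcript, and its value is uncertain.

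Markers of other cell types are given with COL3A1, LYZ and EMCN, which were chosen after their values were seen. COL3A1, a fibroblast collagen, was at 2.81 and 61.54 FPKM in siControl 1 and 2, and at 3.62 and 22.33 FPKM in siTRIM46 1 and 2, so it differed more between the file pairs than between the groups. The fibroblast markers (3 genes, camera adjusted p 0.774) and the leucocyte markers (3 genes, 0.812) did not pass. LYZ lay between 3.54 and 5.31 FPKM, and EMCN, the only tested endothelial marker, between 5.63 and 6.82 FPKM in the 4 libraries. Exons of COL3A1 and LYZ overlap other transcripts.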

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

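The threshold of 0.10, the replicate block together with an estimated correlation, and the test without genes carrying CCTGAC in the 3′ UTR were chosen after the results were seen. The count of 0 genes moved to 3347 with the replicate block, to 98 at an adjusted p under 0.10, and to between 162 and 733 with a library left out; it stayed at 0 under the other scalings, filters, pseudocount, thresholds and limma without trend. Leaving out a library leaves 1 sample in an arm, which is then assumed to vary like the other group. The 2 replicate numbers do not state a pairing, and deviations of same-numbered libraries from their group means correlated at 0.668 across genes. With the block 109 of 139 named genes passed that had not passed before. The camera calls of the DNA replication and homologous recombination lists held with each library left out (adjusted p 4.75e-14 to 9.08e-06 and 3.33e-08 to 5.21e-05) and without CCTGAC genes (2.37e-10 and 2.02e-08). Both calls were lost with an estimated correlation (0.664 each), with fry (0.251 and 0.161) and with the replicate block with an estimated correlation (0.829 each). Of the other lists, 11 passed, and 0 did with an estimated correlation, with fry or with the replicate block and an estimated correlation. The test with an estimated correlation draws on the few residual degrees of freedom of 4 libraries, so its losses cannot be put down to correlation between genes alone. The Fanconi list had an estimated correlation of −0.05, yet its unadjusted camera p went from 4.96e-05 to 0.0498. The replication and G2/M lists had estimated correlations of 0.445 and 0.792. Their unadjusted camera p went from 1.08e-11 to 0.189 and from 6.72e-15 to 0.212. For such lists both may weigh, and their shares were not separated. For fry the cause was not tested. The ribosomal list was also lost with no filter (0.233) and without CCTGAC genes (0.109). The interferon list passed with no filter (0.0455) and without CCTGAC genes (0.0429), and the nucleolar list without CCTGAC genes (0.0155). With the block, no list call was lost but that of nucleotide excision repair. The log2 fold change of TRIM46 was −0.48 with a pseudocount of 0.1, in place of −0.26, as a smaller pseudocount shrinks low genes less; no value under quantile normalization was computed. The planned test on recovered read counts was not run, since no whole reads could be recovered, and depth stays unknown.

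Results whose sign turned all lay near 0 or rested on single libraries, and the cause was not tested; for a list, the sign is the direction of camera against other genes. With the replicate block these were the lists of TRIM46 neighbours (adjusted p 0.978) and drug transport (0.994), and with an estimated correlation as well both (0.995). With median scaling KRTCAP2 (log2 fold change 0.000515), MTX1 (0.012) and the neighbours (0.9996) turned. With quantile normalization it was DCST2 (−0.051), MTX1 (0.022), POLE3 (−0.068), the neighbours and the RNA interference list (0.938 each). With no filter it was non-homologous end joining (0.966), TNF response (0.874) and apoptosis (0.998), and without CCTGAC genes the neighbours (0.987). With a library left out, log2 fold changes ran from −0.013 to 0.59 for EFNA3, −0.011 to 0.61 for COL1A1, −0.12 to 1.09 for COL5A1, −0.55 to 0.12 for POLE4, −0.24 to 0.69 for EFNA1, −0.45 to 0.19 for RNASEH1, −0.47 to 0.80 for THBS3, −1.05 to 0.64 for MUC1, −0.026 to 0.14 for CLK2, −0.37 to 0.46 for DCST2, −0.43 to 0.40 for KRTCAP2, −0.071 to 0.064 for MTX1, −0.093 to 0.59 for SSBP1, −0.20 to 0.31 for RNASEH2B and −0.45 to 0.45 for POLE3. Adjusted p values of lists that turned ran from 0.668 to 0.972 (neighbours), 0.00177 to 0.935 (nucleolar), 0.745 to 0.972 (RNA interference), 0.0771 to 0.290 (fibroblast markers), 4.93e-10 to 0.1996 (interferon), 0.0636 to 0.895 (TNF), 0.0246 to 0.959 (immediate early), 1.72e-05 to 0.922 (ribosomal) and 0.252 to 0.765 (drug transport).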

Other observations

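The search over words, the comparison with words of the same bases, the comparison of site classes, the search of coding sequences, the look at the TRIM46 transcript, the count of siRNA groups and the correlation of deviations were tests chosen after the results were seen; the other tests here were written before the values they measure. The 2 file pairs differed from each other about as much as the groups did (median absolute log2 difference 0.26 against 0.28). With the group in the fit, limma called 2406 genes between replicate 2 and replicate 1 (1425 higher and 981 lower in replicate 2). Among genes chosen after their values were seen, MGP, a matrix protein, was at 38.22 and 223.02 FPKM in siControl 1 and 2 and at 15.84 and 32.78 FPKM in siTRIM46 1 and 2. AREG, an EGFR ligand, was at 4.16 and 32.93 FPKM in siControl and at 2.02 and 6.79 FPKM in siTRIM46. S100A16 went the other way, at 122.55 and 16.41 FPKM in siControl and 97.68 and 15.66 FPKM in siTRIM46, as did PMP22, whose exons overlap another transcript, at 23.95 and 3.92 FPKM and at 23.23 and 6.69 FPKM. Interferon-stimulated genes were higher in replicate 2 (median log2 difference 0.76, camera adjusted p 0.000148 at the preset correlation, but 0.784 with an estimated correlation).

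A word of 7 bases, in 3′ UTRs and also in coding sequences, marked genes that were lower in siTRIM46. Of 16363 words in the 3′ UTRs of 11412 genes, GCCTGAC, present in 1064, had the lowest score (z −14.57), followed by the overlapping words CCTGACA (−9.84) and TGCCTGA (−8.10). The z was −14.41 and −13.11 in the 2 file pairs and −1.50 for the difference between replicate numbers. The highest z of any word was 3.49, and the lowest in 200 shuffles of genes was −5.28. Genes with GCCTGACA (278) had a median log2 fold change of −0.26 (95% bootstrap interval −0.33 to −0.18), those with GCCTGAC alone (786) −0.17 (−0.20 to −0.13), those with CCTGACA alone (762) −0.07, and those with CCTGAC alone (1800) 0.00. Genes with no site (7786) had a median of 0.08. Coding sequences were searched in 7785 genes with no site in the 3′ UTR. GCCTGAC again had the lowest score of 16384 words there (z −10.24), followed by CCTGACA (−7.82). The 971 genes with GCCTGAC only in the coding sequence had a median of −0.133. The 6815 genes with neither a site nor GCCTGAC in the coding sequence had a median of 0.101. SUCLG1, a subunit of a citric acid cycle enzyme, was at 63.97 and 43.58 FPKM in siControl and 13.04 and 10.77 FPKM in siTRIM46. RAD21, a cohesin subunit, was at 121.85 and 105.99 FPKM in siControl and 43.37 and 33.59 FPKM in siTRIM46; both carry GCCTGACA and were chosen after their values were seen, and exons of RAD21 overlap other genes.

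As a hypothesis, this pattern may come from repression through the seed of the TRIM46 siRNA, apart from its intended target. The gap to genes with no site follows from how the word was picked, so sites were compared with each other. The median of genes with GCCTGACA lay −0.09 (95% bootstrap interval −0.17 to −0.0024) from that of genes with GCCTGAC alone. This gap may be in part fixed too, since GCCTGACA joins the 2 lowest words of the same search. The median of genes with GCCTGAC alone lay −0.032 (−0.082 to 0.017) from that of 971 genes with GCCTGAC only in the coding sequence. The 2 sets were unlike: the coding set kept genes with GCCTGACA, and the 3′ UTR set left them out. In the first file pair that difference was −0.044 (−0.090 to −0.00050) and in the second −0.013 (−0.065 to 0.046). Base composition is argued against, with limits: UTR length and base content were fitted out before scoring, and GCCTGAC was picked as the lowest word. The lowest z of 416 other words of the same bases was −2.93, against −14.57 for GCCTGAC. Seed repression would act more in 3′ UTRs than in coding sequence. The interval against coding sequence includes 0 over the 4 libraries and in the second file pair, though not in the first. Because the 2 sets differ in GCCTGACA, this comparison cannot decide the question. Seed repression therefore cannot be told apart here from another effect that goes with the word. The TRIM46 transcript carries GCCTGACA once, in its coding sequence (chromosome 1, 155177211 to 155177217 for the first 7 bases), as do 6.10% of 2312 transcripts of similar length, and the siRNA sequence was not given in the sources used here.

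For the lower level of the DNA replication machinery list, the tables argue against seed sites in the 3′ UTRs of its own genes as the whole cause. Its 26 genes with no site had a median of −0.82, which was −0.90 from that of all genes with no site, and its 22 genes with neither a site nor GCCTGAC in the coding sequence had a median of −0.63. Transcript length and GC content are argued against too, since the median stayed at −0.77 after a fit on length, GC content and level was removed. The lower level was not particular to this list, as the G2/M and G1/S lists had medians of −1.001 and −0.92. What stays open is whether the lower level follows the fall of TRIM46 mRNA, to 69.1% of siControl, or other effects of the siRNA. Such effects could include lower levels of upstream genes with sites. The fall of TRIM46 and other effects of the siRNA cannot be told apart here. The number of groups given a TRIM46 siRNA was 1, and no group had TRIM46 put back. The sources used here do not say whether its libraries received the same siRNA.

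The 0 genes called without and 3347 called with the replicate block are consistent with a difference shared by the libraries of one replicate number, as their deviations from the group means correlated at 0.67 across genes. Transcript length bias between the file pairs is argued against as the whole cause, since the correlation was still 0.63 after length, GC content and level had been fitted out. Such a shared difference could come from the cultures, the libraries or the processing; no biological explanation was tested.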
